A study of Mus musculus with 12 samples.

How the data were processed

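RNA of sorted NKT cells was measured in 12 libraries, 3 each of cKO and YFP+ cells from thymus and from liver. Per the labels' protocols, thymocytes were depleted of CD4+, CD8+ and DP cells before the sort, total RNA was turned into cDNA with the SMARTer Ultra Low Input kit, and libraries were made with a TruSeq or a ThruPLEX kit. The labels do not say which library had which kit. The values are FPKM (fragments scaled by transcript length and by the mapped total of a library), which the authors deposited as 1 table per tissue. Per the submitters' processing notes they come from TopHat2 (version 2.8.0 as the notes give it) and Cufflinks 2.1.1 on the mouse build mm9. The file names point to paired-end reads for the thymus and single-end reads for the liver, and the 2 tables were normalized separately. FPKM already divide by transcript length and by the mapped total. Abundant transcripts in one library lower all its other values, and a difference in transcript integrity or length selection shifts short against long genes. Near-identical genes such as the Klra family, the globins and the Hspa1 pair share reads that Cufflinks divides among them by a model. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

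Groups were taken from the titles. The column headers of the deposited liver values name the same groups as the titles. The description field of the 6 liver libraries names the opposite mouse, and whether it or the titles are right is not settled. Each table has 23284 genes, and 0 columns of values were left unmapped. FPKM carry no read totals. Comparing genes listed between 0.015 and 0.1 FPKM across libraries, the modal ratio put the relative denominators at 0.933 to 1.11 of that of cKO replicate 1 of the same tissue, and absolute depth stays unknown. On average 4211 ± 169 genes were listed at 0 in thymus cKO, 5006 ± 639 in thymus YFP+, 6786 ± 73.7 in liver cKO and 8844 ± 38.0 in liver YFP+ libraries (SD, n = 3), and a value of 0 can be a failed estimate. The 10 highest genes held 14.8 to 19.0% of the sum of a library. Libraries of a group correlated at 0.972 to 0.991 in the thymus and 0.978 to 0.988 in the liver (Pearson r of log2 values across genes), and libraries of different groups at 0.957 to 0.97 and 0.96 to 0.963. No pair was alike enough to be 1 library deposited again.

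The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with values as deposited, genes with a mean of at least 1 FPKM over the fitted libraries, and Benjamini-Hochberg adjustment at 0.05. The pseudocount of 1 makes a fold change understate the change of low genes. Before the data were examined, the unit was unknown, and this test was fixed for the case of FPKM. The 3 comparisons were cKO against YFP+ in the thymus, the same in the liver, and the difference between these differences (liver minus thymus), fitted on all 12 libraries. In the last, a constant offset between the tables on this log2 scale cancels for each gene. A difference in the scale of the FPKM does not fully cancel for low genes, because of the pseudocount. Comparisons of levels between liver and thymus were planned only for a joint table and were left out. The 22 gene lists, the named-gene rule, the tests and the alternatives were fixed before the data were examined. Programme lists are NKT1 and type 1 effector, cytotoxic granule and killing, NK receptors, NKT2, NKT17, immature thymic NKT, and egress, homing and adhesion. General lists are T cell receptor and T lineage core, immediate early and activation, cell cycle, interferon-stimulated, glycolysis and oxidative phosphorylation. The other lists are markers of DP thymocytes, NK cells and type 1 innate lymphoid cells, gamma-delta T cells, B cells, myeloid cells, hepatocytes, liver endothelium and stroma, thymic epithelium and erythroid cells. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. With the estimated correlation, the calls of the immature NKT, cell cycle and DP marker lists in the liver and of the DP marker list between tissues held, and the other calls were lost. Fry tests a list by itself and not against the other genes. Within tissues, 8 lists that camera left uncalled passed with fry, and 1 camera call, that of egress genes in the thymus, was lost. Genes are listed under the symbols of the tables, such as Folr4 and Pkm2. The text names, per tissue, up to 3 genes of each list that passed and whose groups did not overlap, by size of change, the 6 largest such increases and the 6 largest decreases, and always Rag2, Rag1, Zbtb16, Tbx21, Gata3, Ifng, Il4, Il17a, Prf1, Gzmb, Cd4 and Cd8a. For the difference between tissues it names the 5 genes with the smallest p. Of the genes this rule picks, 2 are withheld for evaluation and not reported here. Genes outside this rule are said to have been chosen after their values were seen, or serve as values of the libraries that stood apart.

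Alternatives were a pseudocount of 0.1, no filter and a filter at a mean of 5 FPKM, quantile normalization, median-ratio scaling, the replicate number as a block, array weights, all 12 libraries in 1 fit, a call threshold with at least 2-fold change, leaving out each library, the liver groups by description, and, added later, removing the trend with transcript length in each library. Transcript length is the median over the transcripts of a gene in GENCODE M21, matched by symbol for 98.8% and 98.6% of tested genes, and was used for no coordinates. On simulated values for 9087 thymus genes, the fit recovered 96% of changes of 1 and 95% of changes of 2 on the log2 scale, with 4.98% of 201 calls false. For 9573 liver genes it recovered 80% and 95%, with 4.89% of 184 calls false, and for the difference between tissues over 9722 genes 77% and 96%, with 5.98% of 184 calls false. The simulated noise was drawn for each gene separately, with no shift shared by the genes of a library. These rates may therefore not hold for the real libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.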

Results

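RNA was sequenced from natural killer T (NKT) cells, T cells that recognise lipids presented by CD1d, sorted from the thymus and the liver of C57BL/6 mice. The sort kept live CD4- CD8- CD45R- cells that bound CD1d dimer and carried a T cell receptor beta chain. The 12 libraries fall into 4 groups of 3. In each tissue, NKT cells of double-negative (DN) origin (cKO) stand against NKT cells of double-positive (DP) origin (YFP+). The cKO mice lose a floxed Rag2 gene at the DP stage of thymocyte development through a Cre under the E8III enhancer. In the YFP+ mice the same Cre marks cells through a Rosa26 reporter. The comparison asks how NKT cells that arise before the DP stage differ from those that pass through it. Each origin came from its own kind of mouse, and only the cKO mice lose Rag2. An effect of the origin of the cells therefore cannot be told apart from an effect of the mouse they developed in. For the 6 liver libraries the title names one mouse and the description the other. The column headers of the deposited liver values name the same groups as the titles. The groups used here follow the titles, and every liver direction is mirrored if the descriptions hold. Each table lists FPKM for 23284 genes. The FPKM of a library summed to 192205 ± 3800 in thymus cKO and 204548 ± 7249 in thymus YFP+ (SD, n = 3). In the liver the sums were 457319 ± 7498 in cKO and 537792 ± 25419 in YFP+. Read totals are not part of the tables, so the depth of a library is unknown. Thymus and liver were normalized in separate tables, and levels are compared within a tissue only.

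The targeted gene was read first. In the thymus Rag2, a subunit of the recombinase that assembles antigen receptor genes, was listed at 0 in 5 of 6 libraries and at 0.015 FPKM in cKO replicate 2. In the liver Rag2 was listed at 0 in all 3 libraries titled cKO, and at 1.365, 0.985 and 1.075 FPKM in those titled YFP+. Rag1, the other subunit, was at 0.196, 0.146 and 0.223 FPKM in liver cKO and at 1.957, 1.328 and 1.886 in liver YFP+, and in the thymus at no more than 0.081 FPKM in any library. Neither gene reached the mean level at which genes were tested.

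In the thymus, the cKO libraries held less RNA of the tested NKT2 and most NKT17 genes and of the receptor PD-1. They held more of several Ly49-type NK receptors, of Ccl5 and Ifng, and of 10 of 17 immediate early and activation genes. Whether the RNA per cell or the mix of sorted cells differed is not known. The calls of these NKT2, NKT17 and immediate early lists were lost with an estimated correlation (adjusted p = 0.206 for each). Of 25 tested NK receptor genes 10 were higher and 6 lower, and that list call was lost too (0.274). Ccl5 and Ifng were the only 2 of 19 NKT1 and type 1 effector genes that passed as higher. Another 6 passed as lower, and that list did not pass with camera (adjusted p = 0.684). Pdcd1, which encodes the inhibitory receptor PD-1, was at 0.539 ± 0.212 against 25.96 ± 7.82 FPKM (cKO against YFP+, mean ± SD, n = 3, as throughout), with an adjusted p of 3.36e-05. Zbtb16, which encodes PLZF, the transcription factor of innate-like T cells, was at 3.76 ± 0.565 against 12.3 ± 1.26 FPKM (adjusted p = 2.38e-04). Ccl5, a chemokine of effector T and NK cells, was at 1159 ± 310 against 253 ± 17.0 FPKM (adjusted p = 2.19e-04), and Ifng, the type 1 cytokine, at 58.7 ± 15.9 against 18.2 ± 6.44 FPKM (adjusted p = 0.00824). Klra7, an inhibitory Ly49 receptor, was at 246 ± 19.4 against 30.3 ± 2.41 FPKM (adjusted p = 3.73e-06).

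Of 9097 genes tested in the thymus with limma on log2(FPKM + 1), 1429 passed at an adjusted p of 0.05, 240 higher and 1189 lower in cKO. The median gene lay at -0.16 on the log2 scale in the thymus and at -0.11 in the liver, and fold changes below are on the log2(FPKM + 1) scale relative to it unless said otherwise. With the libraries rescaled by median ratios the thymus count was 789, 367 higher and 422 lower, of which 659 were shared with the first count. The count moved with each library left out: 2408 without cKO replicate 1, 645 without cKO replicate 2, 558 without cKO replicate 3, and 596, 634 and 472 without YFP+ replicates 1, 2 and 3. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

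All 8 tested genes of the NKT2 list were lower in cKO thymus (8 of 8 adjusted over the list alone, and 7 of 8 with median-ratio scaling). The list moved down in the camera test (adjusted p = 1.63e-07, but adjusted p = 0.206 with an estimated correlation). Il4, the type 2 cytokine, was at 0.673 ± 0.273 against 4.22 ± 0.211 FPKM and Il17rb, the receptor for IL-25, at 1.33 ± 0.503 against 8.68 ± 0.614. Folr4, a folate receptor family member, was at 1.02 ± 0.630 against 9.06 ± 2.18 FPKM and Slamf6, a SLAM family receptor used in NKT cell selection, at 0.0247 ± 0.0158 against 2.39 ± 1.17. Gata3, the type 2 transcription factor, differed less, 43.7 ± 1.58 against 53.5 ± 2.05 FPKM (adjusted p = 0.0323). Its call ended with median-ratio scaling (adjusted p = 0.196). Among fits without 1 library it was kept only without cKO replicate 1 (adjusted p = 0.0175). The others gave 0.0883 without cKO replicate 2, 0.106 without cKO replicate 3, and 0.0832, 0.0755 and 0.0941 without YFP+ replicates 1, 2 and 3.

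Of the NKT17 list 10 of 11 tested genes were lower and none higher (11 lower adjusted over the list alone). The list moved down (adjusted p = 7.78e-09, but adjusted p = 0.206 with an estimated correlation). Il23r, a subunit of the IL-23 receptor, was at 0.655 ± 0.0980 against 3.86 ± 0.997 FPKM, and Blk, a Src family kinase, at 2.31 ± 0.697 against 12.01 ± 2.96. Il17a was below the tested level, at no more than 0.251 FPKM in any thymus library.

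NK receptor genes moved both ways. Of 25 tested in the thymus 10 were higher and 6 lower in cKO (12 and 8 adjusted over the list alone). The list moved up (adjusted p = 2.8e-07, but adjusted p = 0.274 with an estimated correlation). Besides Klra7, Klra8 was at 61.9 ± 22.1 against 19.8 ± 4.18 FPKM, and the lectin-like receptor Klri2 was at 43.7 ± 7.22 against 10.7 ± 1.54. Klra23 and the pseudogene Klra13-ps, at 615 ± 91.4 against 88.4 ± 11.5 and 1295 ± 200 against 184 ± 23.5 FPKM, are close copies of other Ly49 genes, and reads shared within this family leave the level of each member uncertain. Of 6 tested markers of NK cells and type 1 innate lymphoid cells, 3 were higher and 2 lower (3 and 2 adjusted over the list alone). The list moved up (adjusted p = 0.00119, but adjusted p = 0.249 with an estimated correlation). They included Klre1, a receptor of NK cells, at 114 ± 7.64 against 49.7 ± 2.02 FPKM, and Gzma, granzyme A, at 60.0 ± 17.0 against 110 ± 1.73. The Gzma call was lost without YFP+ replicate 1, 2 or 3 (adjusted p = 0.0546, 0.0503 and 0.0685), with no filter on low values (0.0587) and with the length trend removed (0.0501).

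The 19 genes of the NKT1 and type 1 effector list gave 2 higher and 6 lower (3 and 9 adjusted over the list alone). The list did not pass (adjusted p = 0.684, test direction up, median -0.01). Id2, an inhibitor of E proteins, was lower at 468 ± 57.9 against 782 ± 52.8 FPKM. Tbx21, which encodes T-bet, was at 65.6 ± 9.13 against 73.9 ± 3.96 FPKM (adjusted p = 0.241), and passed only without cKO replicate 1 among fits without 1 library (adjusted p = 0.0332), and with array weights (0.0431). Of 15 cytotoxic granule and killing genes 5 were lower (2 higher and 7 lower adjusted over the list alone, and 2 higher and 4 lower with median-ratio scaling). The list did not pass (adjusted p = 0.553, but 0.0316 with fry). Serpinb9, an inhibitor of granzyme B, was at 13.2 ± 1.03 against 24.1 ± 3.14 FPKM. Fasl, the Fas ligand, was at 22.6 ± 5.95 against 36.5 ± 5.88 FPKM. This call ended with median-ratio scaling (adjusted p = 0.0844). It also ended in every fit without 1 library (0.0718 to 0.132) except that without cKO replicate 1 (adjusted p = 0.0025). Gzmb, granzyme B, was at 288 ± 31.3 against 231 ± 13.9 FPKM and just missed the threshold (adjusted p = 0.0541), passing in 5 alternatives, among them median-ratio scaling (adjusted p = 0.0133), with 0.0103 to 0.0441 there. Prf1, perforin, was at 23.2 ± 1.81 against 22.1 ± 0.628 FPKM (adjusted p = 0.565).

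Of 11 tested genes linked to immature thymic NKT cells 7 were lower and 2 higher (7 and 3 adjusted over the list alone). The list as a whole missed the threshold in the camera test (adjusted p = 0.0867), though not with fry (adjusted p = 0.00277). It passed without cKO replicate 2 (0.00491), cKO replicate 3 (0.0111) or YFP+ replicate 3 (0.036), and with median-ratio scaling (0.00695), quantile normalization (0.003), no filter on low values (9.09e-07) or the length trend removed (0.00163). Lef1, a transcription factor of early T cells, was at 5.95 ± 0.935 against 23.6 ± 2.04 FPKM, the membrane protein gene Itm2a at 16.3 ± 0.989 against 43.6 ± 6.29 and Ldhb, a lactate dehydrogenase subunit, at 1.16 ± 0.0696 against 4.49 ± 0.205. Of 14 egress, homing and adhesion genes 4 were higher and 4 lower (4 and 4 adjusted over the list alone, and 4 and 2 with median-ratio scaling). Klf2, a transcription factor that drives S1pr1, was at 133 ± 5.90 against 63.1 ± 8.15 FPKM and S1pr1, the receptor that guides cells out of the thymus, at 10.8 ± 2.35 against 4.34 ± 0.145. Itgae, the CD103 integrin chain, was lower at 32.2 ± 1.88 against 50.1 ± 1.33. This list moved up (adjusted p = 0.0348, but 0.496 with an estimated correlation and 0.68 with fry). The call was lost without cKO replicate 1 (adjusted p = 0.0979), and with quantile normalization (adjusted p = 0.191), a replicate block or the length trend removed. It was also lost with no filter on low values, where the median turned to -0.08 (adjusted p = 0.815).

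Of 17 immediate early and activation genes 10 were higher and 1 lower in cKO thymus (14 and 1 adjusted over the list alone). The list moved up (adjusted p = 4.15e-18, but adjusted p = 0.206 with an estimated correlation). Fosb, a subunit of AP-1, was at 10.00 ± 5.46 against 0.784 ± 0.341 FPKM. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, were at 528 ± 379 against 5.67 ± 0.769 and 634 ± 457 against 6.78 ± 0.680 FPKM, and their relative Hspa1l at 48.4 ± 34.8 against 0.681 ± 0.204. In these genes cKO replicate 1 stood apart: Hspa1a was at 90.7 FPKM there and at 743 and 751 in the other cKO libraries, and Fosb at 3.72 against 13.7 and 12.6. The same library carried more interferon-stimulated RNA, with Ifit3 at 135 FPKM against 16.3 and 38.7, and haemoglobin RNA, with Hbb-b1 at 40.8 FPKM against 0.034 and 5.51. None of the 21 interferon-stimulated genes passed in limma, overall or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Without cKO replicate 1, however, 12 of them passed as lower, and with array weights 4. The list did not pass (adjusted p = 0.13, test direction up, median -0.05), but moved down without cKO replicate 1 (median -0.65, adjusted p = 0.000535) and up without cKO replicate 2 (median 0.40, adjusted p = 2.36e-05) or cKO replicate 3 (median 0.09, adjusted p = 0.0461). None of 4 tested erythroid markers passed, with 2 at an unadjusted p under 0.05. Their summed FPKM was 40.7 ± 58.3 in cKO and 0.439 ± 0.374 in YFP+.

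The list of 16 tested cell cycle genes did not pass (adjusted p = 0.0808, but 0.0316 with fry). Of these genes 6 were lower (7 adjusted over the list alone, 2 with median-ratio scaling). Among them were the replication helicase genes Mcm2, 11.7 ± 0.473 against 16.7 ± 1.21 FPKM, and Mcm6, 36.4 ± 1.06 against 51.6 ± 5.04. The list passed without cKO replicate 2 (0.0431) or YFP+ replicate 1 (0.00413), and with median-ratio scaling (0.0201), quantile normalization (0.0201), no filter on low values (0.000979) or the length trend removed (0.0169). Of 21 oxidative phosphorylation genes 5 were lower (13 adjusted over the list alone), and with median-ratio scaling none. The list moved down (adjusted p = 0.00653, but adjusted p = 0.638 with an estimated correlation). Of 14 glycolysis genes 2 were lower (3 adjusted over the list alone), and 3 higher and 1 lower with median-ratio scaling (list adjusted p = 0.765). Pfkp, a phosphofructokinase, was at 20.9 ± 0.932 against 28.6 ± 0.270 FPKM. Of 18 T cell receptor and T lineage genes 1 was higher and 6 lower (1 and 7 adjusted over the list alone, 2 and 3 with median-ratio scaling). As a list they did not pass (adjusted p = 0.378, but 0.00567 with no filter on low values and 0.0316 with fry). Sh2d1a, which encodes the SLAM adaptor SAP, was lower at 11.3 ± 0.599 against 20.9 ± 1.92 FPKM, as was the receptor gene Cd6 at 23.7 ± 1.67 against 37.7 ± 5.23. Cenpa, Cox4i1, Cox6c, Sdhb, Pkm2, Pecam1, Thy1 and Mir142 passed only narrowly, at adjusted p of 0.0192 to 0.0437. Each kept its call without cKO replicate 1 and lost it without any other single library, with adjusted p of up to 0.142, except Cenpa without YFP+ replicate 1 (0.00574) and Thy1 without YFP+ replicate 2 (0.0375). All but Thy1 also lost it with median-ratio scaling.

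The largest other differences in the thymus, by size among genes whose groups did not overlap, were lower in cKO. Nrgn, which encodes the calmodulin-binding protein neurogranin, was at 0.396 ± 0.230 against 14.5 ± 4.89 FPKM, Ahr, the aryl hydrocarbon receptor, at 1.11 ± 0.419 against 11.7 ± 0.892, and Atp8a2, a phospholipid flippase, at 0.683 ± 0.163 against 8.81 ± 0.953. Trf, transferrin, the single tested gene of the hepatocyte list, was at 4.80 ± 0.968 against 27.6 ± 2.37 FPKM. Of the 3 tested DP thymocyte markers 2 were lower (2 adjusted over the list alone): Cd4 at 0.429 ± 0.194 against 2.88 ± 0.891 FPKM and Cd1d1, the lipid-presenting molecule, at 6.03 ± 0.818 against 10.97 ± 1.67. Cd8a did not exceed 0.015 FPKM in a thymus library. Fcgr3, an Fc receptor and the 1 tested myeloid marker, was at 1.07 ± 0.0820 against 2.12 ± 0.0689 FPKM. None of 3 gamma-delta T cell markers passed, and 0 had an unadjusted p under 0.05, while no B cell or thymic epithelium marker reached the tested level.

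**Figure D1:**
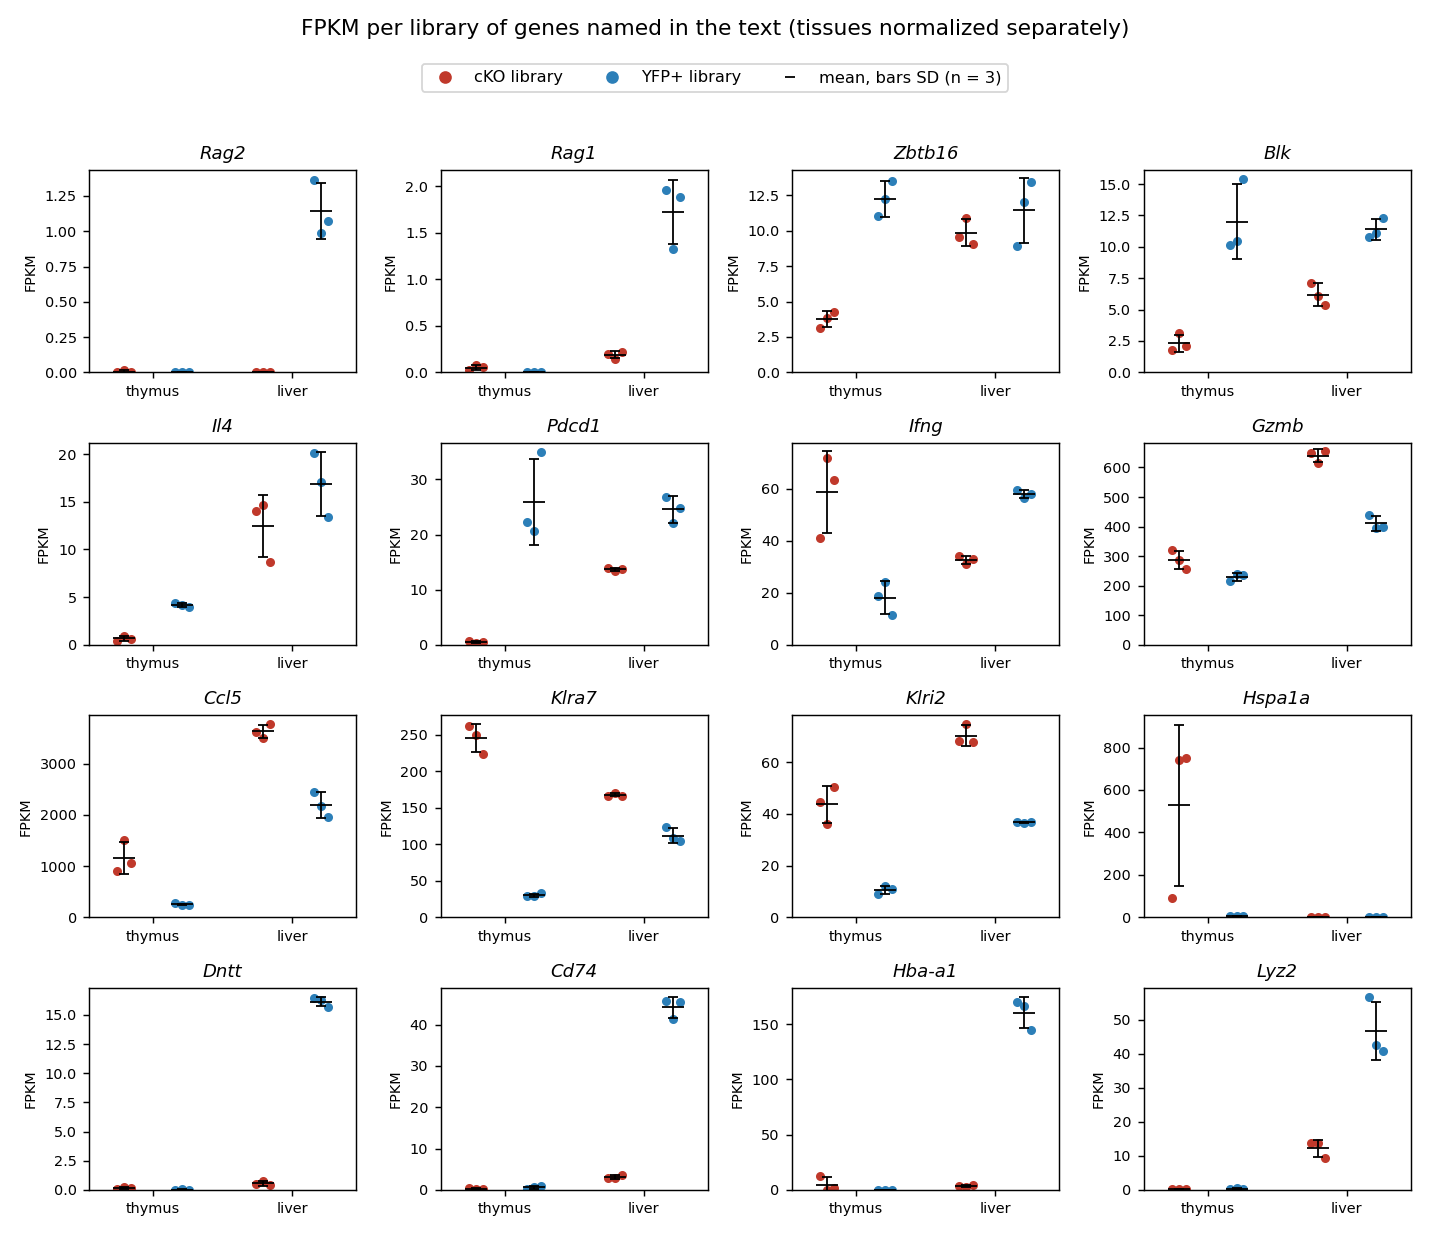
FPKM (vertical axes, linear, from 0) of 16 genes in each of the 12 libraries, as points by tissue and origin, with the mean and SD of each group of 3; thymus and liver come from separately normalized tables. Rag2 is listed at 0 in the liver cKO libraries and lies between 0.985 and 1.365 FPKM in the liver YFP+ libraries, and Hspa1a in thymus cKO replicate 1 lies at 90.7 FPKM, below the 743 and 751 of the other cKO libraries.

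In the liver, with groups by the titles, the cKO libraries held less RNA of genes of immature thymic T cells and of the cell cycle. They also held less of DP thymocyte and red cell genes, and more of 3 genes of gamma-delta T cells. Whether these differences lay in the NKT cells or in other cells of the libraries is not known. Ccr7, the lymph node homing receptor, was at 1.47 ± 0.678 against 12.8 ± 1.51 FPKM (adjusted p = 2.24e-04), and Dntt, terminal transferase, at 0.546 ± 0.199 against 16.1 ± 0.395 (adjusted p = 1.98e-06). Ccnb1, cyclin B1, was at 2.10 ± 0.654 against 12.9 ± 1.44 FPKM (adjusted p = 1.83e-04). Cd74, the invariant chain of MHC class II, was at 3.09 ± 0.481 against 44.2 ± 2.47 FPKM (adjusted p = 8.72e-07). Sox13, a transcription factor of gamma-delta T cells, was higher in cKO at 8.12 ± 1.25 against 0.793 ± 0.267 FPKM (adjusted p = 1.11e-04).

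Of 9591 genes tested in the liver with limma, 2607 passed, 718 higher and 1889 lower in cKO. With median-ratio scaling 2061 passed, 1003 higher and 1058 lower, 1776 of them shared. If the descriptions give the mice, the same 2607 genes are 1889 higher and 718 lower. The count was 1623 without cKO replicate 1, 1644 without cKO replicate 2 and 1539 without YFP+ replicate 2. Shorter transcripts lay lower in cKO liver: the median log2 change before centring was -0.20 in the lowest tertile of transcript length and 0.01 in the highest (Spearman rho 0.244 across genes, which are not independent replicates). In the thymus it was -0.18 and -0.16. The Y-linked gene Eif2s3y, chosen after its values were seen, was at 10.07 ± 0.718 FPKM in liver cKO and 24.77 ± 0.286 in liver YFP+, and listed at 0 in the 6 thymus libraries. A difference in the mix of sexes between the liver groups therefore cannot be told apart from the other differences between them.

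Of 16 tested genes linked to immature thymic NKT cells 14 were lower in cKO liver and none higher (14 adjusted over the list alone, 12 with median-ratio scaling). The list moved down (adjusted p = 3.49e-09, and adjusted p = 0.0311 with an estimated correlation). Cd24a, a surface protein of immature thymocytes, was at 0.0720 ± 0.0852 against 3.92 ± 0.761 FPKM, and Cd81, a tetraspanin, at 0.919 ± 0.531 against 7.80 ± 2.68. Of 7 DP thymocyte markers 6 were lower (7 adjusted over the list alone), and the list moved down (adjusted p = 3.15e-06, and adjusted p = 0.0411 with an estimated correlation). They included Cd8b1 at 0.844 ± 0.233 against 13.1 ± 1.89 FPKM, Endou at 0.160 ± 0.225 against 4.31 ± 0.422 and Cd4 at 1.90 ± 0.528 against 8.44 ± 0.437. Cd8a lay between 0.86 and 1.946 FPKM in the YFP+ libraries and at no more than 0.251 in the cKO libraries. Of 23 cell cycle genes 18 were lower and 1 higher (20 and 1 adjusted over the list alone). The list moved down (adjusted p = 2.92e-07, and adjusted p = 0.0311 with an estimated correlation). Ccnb2, cyclin B2, was at 3.32 ± 0.586 against 13.5 ± 0.554 FPKM and Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 2.79 ± 0.667 against 17.1 ± 4.03.

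Markers of other blood cells moved with the group. All 4 tested erythroid markers were lower in cKO (4 adjusted over the list alone), with Hba-a1 at 3.34 ± 0.622 against 160 ± 13.8 FPKM and Hbb-b1 at 3.04 ± 0.930 against 191 ± 14.2. Hba-a2, Hbb-b2 and Beta-s are near-identical globin copies whose reads cannot be told apart with certainty, and lay at 3.33 ± 0.620 against 160 ± 13.7, 3.08 ± 0.944 against 194 ± 14.4 and 3.44 ± 1.02 against 225 ± 15.1. Of 6 B cell markers 5 were lower and 1 higher (5 and 1 adjusted over the list alone). As a list they moved down (adjusted p = 0.000312, but adjusted p = 0.0706 with an estimated correlation). The MHC class II genes H2-Aa and H2-Ab1 were at 1.58 ± 0.782 against 23.6 ± 3.06 FPKM and 0.658 ± 0.0519 against 19.8 ± 2.04. Of 9 myeloid markers 5 were lower and 1 higher (6 and 1 adjusted over the list alone). These markers moved down as a list (adjusted p = 0.0223, but adjusted p = 0.204 with an estimated correlation). Lysozyme, Lyz2, was at 12.2 ± 2.59 against 46.7 ± 8.63 FPKM, and the complement genes C1qa and C1qb at 0.203 ± 0.202 against 1.95 ± 1.03 and 0.504 ± 0.167 against 3.61 ± 0.605. Ly6d, a surface protein of B cell progenitors, was at 1.91 ± 0.618 against 61.8 ± 2.41 FPKM. The 3 tested gamma-delta T cell markers were all higher (3 adjusted over the list alone): Sox13, Cd163l1, a scavenger receptor, at 8.40 ± 1.78 against 1.98 ± 0.489, and its relative 5830411N06Rik at 4.99 ± 0.184 against 1.47 ± 0.372. Of 3 hepatocyte markers 1 was lower (1 adjusted over the list alone), Trf, at 12.2 ± 1.999 against 38.4 ± 2.33 FPKM, and the 1 endothelial marker tested, Pecam1, was lower at 1.25 ± 0.366 against 3.22 ± 0.571. No thymic epithelium marker reached the tested level.

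Effector genes moved both ways in the liver. Of 19 NKT1 and type 1 effector genes 2 were higher and 8 lower (3 and 9 adjusted over the list alone). As a list they did not pass (adjusted p = 0.0891, but 0.00184 with no filter on low values and 0.00114 with fry). Ifng was at 32.6 ± 1.47 against 57.9 ± 1.57 FPKM, the chemokine genes Ccl3 and Ccl4 at 0.893 ± 0.159 against 3.17 ± 1.16 and 5.73 ± 1.40 against 23.0 ± 4.70, and Bhlhe40, a transcription factor of cytokine-producing T cells, at 10.3 ± 0.971 against 25.5 ± 2.51. Tbx21 was at 18.4 ± 0.486 against 22.4 ± 3.93 FPKM (adjusted p = 0.159). Of 16 cytotoxic granule and killing genes 2 were higher and 5 lower (3 and 6 adjusted over the list alone, 3 and 2 with median-ratio scaling; list adjusted p = 0.626). Gzmb was higher at 640 ± 22.2 against 411 ± 24.6 FPKM, as was Rab27a, which docks lytic granules, at 16.8 ± 0.567 against 10.7 ± 1.70, and the serpin gene Serpinb6b was lower at 38.9 ± 2.70 against 57.4 ± 3.90. Gzma was at 165 ± 10.1 against 235 ± 32.3 FPKM, a call that ended with median-ratio scaling (adjusted p = 0.0632), quantile normalization (0.0692) and the length trend removed (0.0707). Prf1 was at 42.8 ± 1.32 against 35.6 ± 5.78 FPKM (adjusted p = 0.119) and passed without YFP+ replicate 3 (adjusted p = 0.0172), with quantile normalization (0.0226) and with array weights (0.0134). Of 27 NK receptor genes 8 were higher and 13 lower (8 and 14 adjusted over the list alone, 8 and 6 with median-ratio scaling). The list did not pass (adjusted p = 0.959, test direction up, median -0.12). Klri2 was higher at 70.3 ± 3.98 against 36.7 ± 0.0629 FPKM, as was Ncr1, the NKp46 receptor, at 2.19 ± 0.607 against 0.318 ± 0.166, and Klra9 was lower at 502 ± 14.0 against 920 ± 74.2, with reads shared within the Klra family. Of 7 markers of NK cells and type 1 innate lymphoid cells 3 were higher and 2 lower (4 and 3 adjusted over the list alone, 3 and 0 with median-ratio scaling). As a list they did not pass (adjusted p = 0.159, but 0.0168 with fry, direction up). Klre1 was at 194 ± 4.04 against 139 ± 15.1 FPKM.

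Of 10 NKT2 genes 5 were lower in cKO liver (5 adjusted over the list alone; adjusted p = 0.00338, but adjusted p = 0.085 with an estimated correlation). Plac8 was at 1.85 ± 0.419 against 45.6 ± 2.14 FPKM, Slamf6 at 0.586 ± 0.319 against 4.83 ± 0.932 and Folr4 at 6.49 ± 0.304 against 14.2 ± 0.859. Zbtb16 was at 9.86 ± 0.949 against 11.4 ± 2.31 FPKM (adjusted p = 0.408), Gata3 at 81.5 ± 1.89 against 88.1 ± 10.7 (adjusted p = 0.467) and Il4 at 12.5 ± 3.25 against 16.9 ± 3.36 (adjusted p = 0.168, but 0.0448 with a replicate block). Of 10 NKT17 genes 6 were lower (6 adjusted over the list alone, 3 with median-ratio scaling). The NKT17 list moved down here too (adjusted p = 0.0249, but adjusted p = 0.154 with an estimated correlation), a call lost without cKO replicate 3 (adjusted p = 0.0515). Nrp1, neuropilin 1, was at 0.851 ± 0.366 against 3.33 ± 1.10 FPKM and Blk at 6.2 ± 0.883 against 11.4 ± 0.831. The calls of both lists ended when genes were required to reach a mean of 5 FPKM (adjusted p = 0.141 for NKT2 and 0.367 for NKT17). Il17a was listed at 0 in the 3 cKO libraries and at 0.27, 0.297 and 0.397 FPKM in the YFP+ libraries.

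Of 17 immediate early and activation genes 9 were lower in cKO liver (10 adjusted over the list alone; adjusted p = 0.000247, but adjusted p = 0.085 with an estimated correlation). The AP-1 gene Fos was at 16.4 ± 1.08 against 73.6 ± 6.24 FPKM, the phosphatase gene Dusp1 at 30.2 ± 1.98 against 130 ± 11.1 and the stress factor gene Atf3 at 0.664 ± 0.519 against 6.47 ± 0.0910. Of 17 egress, homing and adhesion genes 7 were higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.000312, but adjusted p = 0.208 with an estimated correlation). The chemokine receptor gene Ccr2 was at 24.3 ± 1.13 against 12.3 ± 0.623 FPKM and Itgae at 44.2 ± 1.78 against 25.5 ± 3.85. Of 21 oxidative phosphorylation genes 14 were lower (16 adjusted over the list alone, 4 with median-ratio scaling). As a list they moved down (adjusted p = 0.000346, but 0.241 with an estimated correlation). Cox5b was at 118 ± 3.97 against 176 ± 8.11 FPKM and Ndufs6 at 72.9 ± 1.30 against 108 ± 11.8, the latter without a call under quantile normalization (log2 fold change -0.28, not shifted for the median gene, adjusted p = 0.057). Of 14 glycolysis genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone, 1 and 1 with median-ratio scaling; list adjusted p = 0.959, test direction down, median 0.10), with the mutase gene Pgam1 at 18.2 ± 1.35 against 27.2 ± 1.95 FPKM. Of 21 interferon-stimulated genes 5 were lower (5 adjusted over the list alone, 2 with median-ratio scaling). As a list they did not pass (adjusted p = 0.409, but 0.0243 with no filter on low values and 0.00224 with fry). Ifi27l2a was at 256 ± 12.6 against 511 ± 65.4 FPKM and Rtp4 at 48.8 ± 3.03 against 73.3 ± 6.27, and both lost the call with all 12 libraries in the fit (adjusted p = 0.145 and 0.211). Of 18 T cell receptor and T lineage genes 1 was higher and 4 lower (1 and 7 adjusted over the list alone). As a list they did not pass (adjusted p = 0.393, but 0.0375 with no filter on low values and 0.000756 with fry). Sh2d1a was at 24.4 ± 0.644 against 64.8 ± 9.90 FPKM and the co-stimulatory receptor gene Cd28 at 36.7 ± 0.599 against 56.5 ± 3.15. The call of Bcl11b was lost without cKO replicate 3 (adjusted p = 0.0567) or YFP+ replicate 2 (0.06), and that of Uqcrq without cKO replicate 1 (0.0545) or YFP+ replicate 2 (0.0526). Gapdh lost its call without cKO replicate 1 (0.0781), cKO replicate 2 (0.0633) or YFP+ replicate 2 (0.0646). Gbp2 lost it without cKO replicates 1 (0.0788) or 3 (0.0586) or YFP+ replicates 2 (0.0649) or 3 (0.052), and Rora kept it only without YFP+ replicate 1 (0.0029), with up to 0.15 otherwise. Uqcrq, Gapdh, Gbp2 and Rora, and the kinase gene Pgk1, also lost the call with median-ratio scaling (adjusted p = 0.051 to 0.149).

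The largest other increases in cKO liver were in Ccr10, a skin and mucosa homing receptor, at 24.4 ± 3.52 against 4.99 ± 1.56 FPKM, the relaxin gene Rln3 at 21.3 ± 4.55 against 4.004 ± 0.270 and the axonal adhesion gene Cntnap1 at 5.41 ± 0.116 against 0.629 ± 0.359. Gm6213, a predicted gene, was at 6.85 ± 2.08 against 0.990 ± 0.872 FPKM. The pseudogene Speer7-ps1 was at 3.344, 4.909 and 2.224 FPKM in cKO and listed at 0 in the 3 YFP+ libraries.

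**Figure D2:**
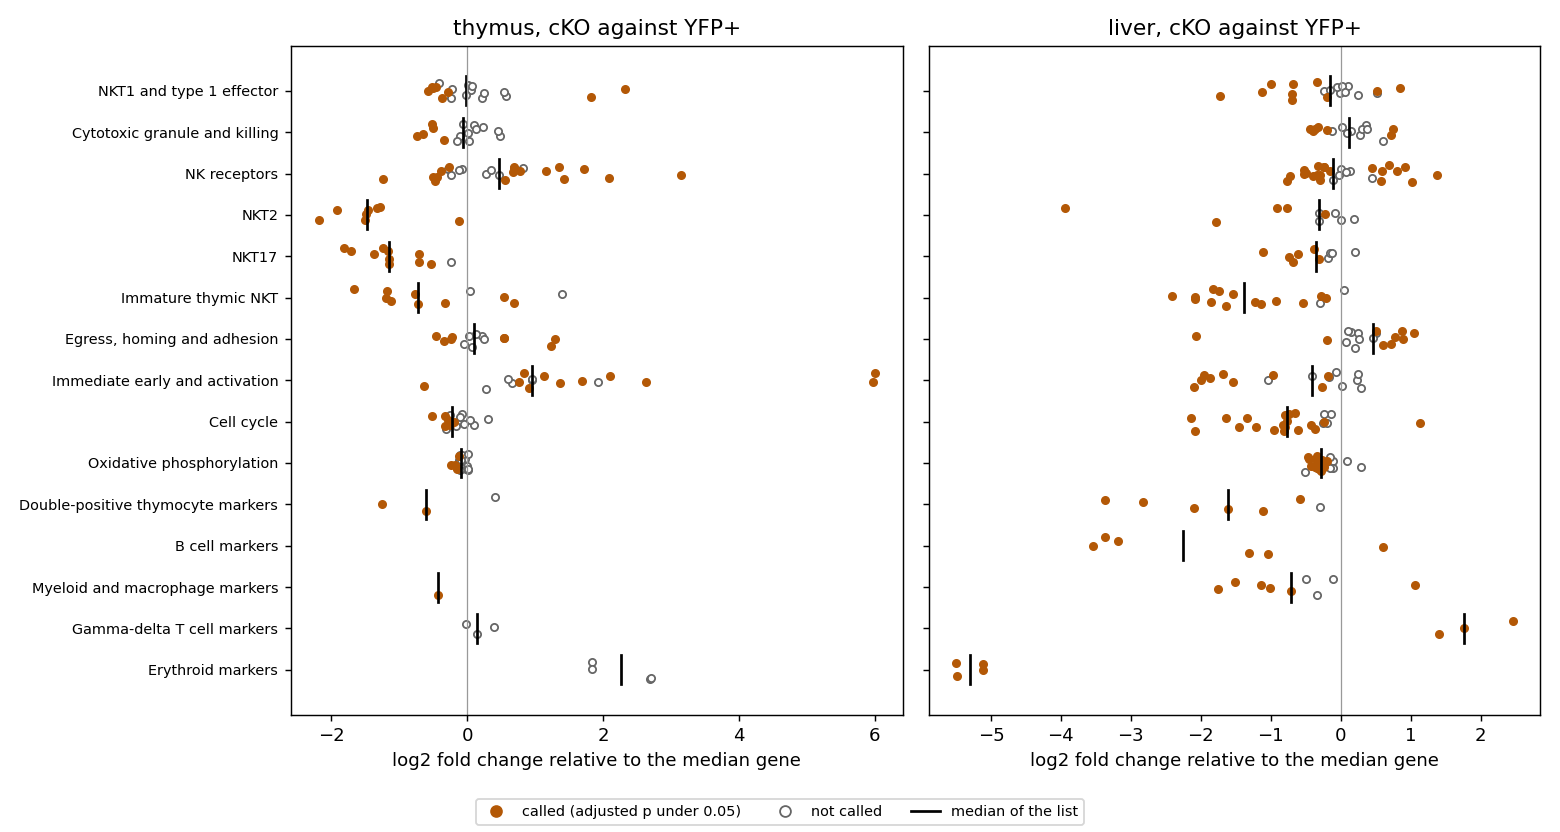
Log2 fold change of cKO against YFP+ relative to the median gene (horizontal axes) for the tested members of 15 gene lists in thymus (left) and liver (right), where each point is a gene, filled if it passed at an adjusted p of 0.05, and the black bar is the median of the list. All 8 NKT2 genes lie left of 0 in the thymus, and the 4 erythroid markers lie left of -5 in the liver.

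The fold changes of the 2 tissues were weakly related across the 8372 genes tested in both (r = 0.136, Spearman rho 0.183, across genes, which are not independent replicates). Of 469 genes that passed in both, 59 were higher in cKO in both and 321 lower in both, where independent lists of the same sizes would share 12.7 and 226.5. The other 89 moved in opposite directions, where 111.3 would. With median-ratio scaling 259 passed in both, 97 higher in both (30.4 for independent lists), 100 lower in both (41.5) and 62 in opposite directions (71.0). Genes lower in both included Pdcd1, Nrgn, Trf and Slamf6, and Klra7, Klri2 and Ccl5 were higher in both. These directions are by the liver titles.

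**Figure D3:**
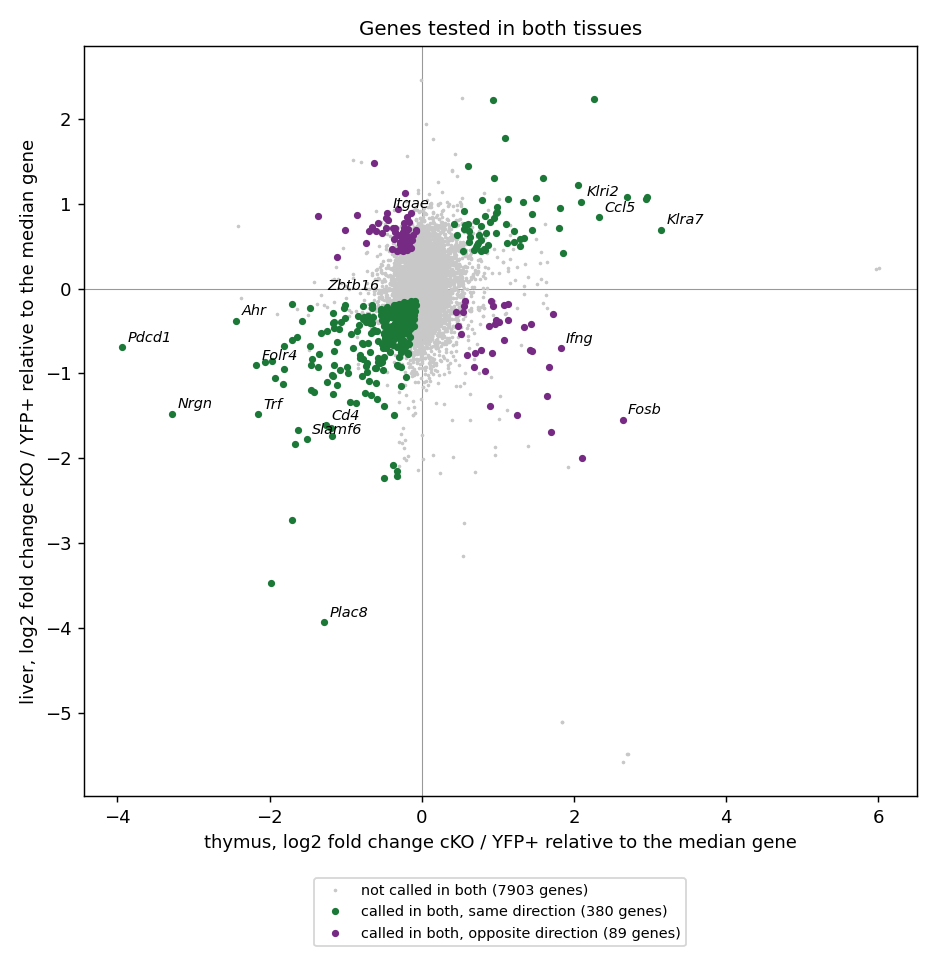
Log2 fold change of cKO against YFP+ relative to the median gene in thymus (horizontal) and liver (vertical) for the 8372 genes tested in both, with 380 genes that passed in both and moved the same way in green and 89 that moved in opposite ways in purple. Pdcd1 and Nrgn lie at the lower left, and Ifng and Fosb, higher in thymus and lower in liver, at the lower right.

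The difference between tissues was tested as the liver difference minus the thymus difference in 1 fit over the 12 libraries. Y-linked RNA differed between the groups in the liver and not in the thymus, so a difference in the mix of sexes does not cancel here. Of 9739 genes 1466 passed, 890 with a more positive and 576 with a more negative difference in the liver (1493 with median-ratio scaling, 854 and 639, 1369 of them shared). Without YFP+ thymus replicate 1 the count was 976. The 5 genes with the smallest p were Dntt (log2 difference -3.62 ± 0.15, SE, not shifted for the median gene, as for all genes here), the class II genes H2-Ab1 (-3.68 ± 0.17) and H2-Eb1 (-2.77 ± 0.15), Ly6d (-4.63 ± 0.25) and Klra7 (-2.40 ± 0.12). Ifng and Fosb, higher in cKO thymus and lower in cKO liver, differed by -2.47 ± 0.32 and -4.13 ± 0.48. Among lists, NKT2 (median 1.15, adjusted p = 0.022, but adjusted p = 0.147 with an estimated correlation) and NKT17 (median 0.92, adjusted p = 0.000318, but adjusted p = 0.0765 with an estimated correlation) were less reduced in the liver. Immediate early genes (median -1.95, adjusted p = 7.45e-13, but adjusted p = 0.0765 with an estimated correlation), cell cycle genes (median -0.61, adjusted p = 2.76e-06, but adjusted p = 0.0765 with an estimated correlation) and genes of immature NKT cells (median -0.51, adjusted p = 0.000141, but adjusted p = 0.0765 with an estimated correlation) had a more negative difference in the liver. So did NK receptors (median -0.27, adjusted p = 0.000319, but adjusted p = 0.322 with an estimated correlation), myeloid markers (median -0.91, adjusted p = 0.00381, but adjusted p = 0.147 with an estimated correlation) and DP thymocyte markers (median -0.94, adjusted p = 2.95e-08, and adjusted p = 0.0421 with an estimated correlation). If the descriptions give the mice, these differences are not the same genes with the sign turned: the count is then 3390 (2249 with median-ratio scaling), and each difference above has another value.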

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

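The test of the difference between tissues was planned, the splits of the libraries and the length test were set before their results were seen, and the tests of cell shares, of DP thymocyte RNA, of exchanged liver titles, of strain DNA and of shared Klra reads were chosen only after the patterns were seen.

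The cKO against YFP+ difference itself differed between liver and thymus for 1466 genes in limma, by the liver titles. Differences below are log2 values, liver minus thymus, not shifted for the median gene, which lay at 0.06. By list, the median difference was 1.15 for NKT2, 0.915 for NKT17, -0.267 for NK receptors, -0.508 for immature thymic NKT, -1.95 for immediate early and activation, -0.614 for cell cycle, -0.945 for DP thymocyte markers and -0.907 for myeloid markers, each relative to the median gene. With an estimated correlation only the call of the DP thymocyte markers held (adjusted p = 0.0421), and the other 7 were lost (0.0765 to 0.322). Among genes lower in cKO thymus, the difference was 3.3 for Pdcd1, 2.12 for Ahr, 2.33 for Atp8a2, 1.86 for Nrgn, and 1.66 for Il17rb. It was 1.33 for Folr4, 1.3 for Zbtb16, 1.23 for Il4, 1.25 for Il23r, and 1.18 for Blk. It was 0.72 for Trf, 0.713 for Cd6, 0.588 for Id2, 0.513 for Serpinb9, 0.499 for Pfkp and 1.4 for Itgae, which was higher in cKO liver. Genes higher in cKO liver gave 2.53 for Sox13, 1.68 for Cd163l1, 1.05 for 5830411N06Rik, 1.77 for Rln3, 1.71 for Gm6213, 1.52 for Cntnap1, 1.34 for Ccr10 and 1.03 for Ccr2. NK receptor genes gave -2.4 for Klra7, -1.97 for Klra8, -1.84 for Klra13-ps, -1.83 for Klra23, -1.4 for Klra9, -1.01 for Klri2 and -0.7 for Klre1. Stress and activation genes gave -5.71 for Hspa1b, -5.68 for Hspa1a, -4.59 for Hspa1l, -4.13 for Fosb, -4.04 for Fos, -3.97 for Atf3 and -2.87 for Dusp1. Effector and trafficking genes gave -2.47 for Ifng, -1.43 for Ccl5, -1.68 for Ccl4, -1.51 for Ccl3, -1.28 for Bhlhe40, -1.07 for Klf2, -0.735 for S1pr1 and -1.56 for Ccr7. Markers of other cells gave -8.18 for Beta-s, -8.14 for Hbb-b2, -8.12 for Hbb-b1, -6.9 for Hba-a1 and for Hba-a2, and -4.63 for Ly6d. They gave -3.68 for H2-Ab1, -3.32 for H2-Aa, -3.15 for Cd74 and -2.77 for H2-Eb1, and -3.62 for Dntt, -2.83 for Cd8b1, -2.28 for Endou, -1.75 for Lyz2 and -1.66 for C1qb. The remaining genes gave -2.6 for Plac8, -2.17 for Cd24a, -2.09 for Ccnb1, -2.04 for Ube2c, -1.34 for Ccnb2, -0.599 for Pgam1, -0.58 for Cd28, -0.534 for Sh2d1a, -0.524 for Bcl11b and -0.407 for Cox5b.

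For the thymus count, the real split of the 6 libraries gave 1429 genes and the highest other split 0, and for the liver count the real split gave 2607 and the highest other 1. In each, 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the difference between tissues, 3 of 100 drawn splits, the real one included, gave at least the real 1466. These splits shuffle the groups within both tissues at once, so they stand for no cKO against YFP+ difference in either tissue. Their low share therefore does not show that the tissues differ. The highest other, 3390 genes, was the split that exchanges the 2 liver groups as a whole, which is the count if the descriptions give the mice. It follows the structure of the samples, since it adds the liver difference to the thymus difference, and it fell to 2249 with median-ratio scaling. The next highest gave 1470.

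Most tested markers of DP thymocytes (6 of 7), B cells (5 of 6), myeloid cells (5 of 9) and red cells (4 of 4) were higher in the liver libraries titled YFP+, although the sort excluded CD4, CD8 and CD45R. Of the B cell and of the myeloid markers 1 each was lower, and with an estimated correlation both list calls were lost (adjusted p = 0.0706 and 0.204). A single lower share of NKT cells in those sorts would raise all other types alike only if NKT cells carried none of their markers. The summed erythroid markers differed by a log2 amount 4.65 larger than the summed myeloid markers (SE 0.236). But the myeloid sum was already at 82.2 FPKM in cKO (170.6 in YFP+), and the erythroid sum at 12.9 (705 in YFP+). How much of the myeloid sum NKT cells carry is unknown, so this gap does not decide it. Removing the length trend left 18 of 18 called markers with a known length past the threshold. The median log2 change of the called markers, not shifted for the median gene, was -2.03 before and -1.63 after. This argues against a bias to short transcripts as the whole source. DP thymocytes or their RNA in the YFP+ liver libraries are neither excluded nor shown as a source. In all, 10 of the 11 listed DP markers were higher in every YFP+ than in every cKO liver library, with Cd4 at 8.44 ± 0.437 FPKM, Dntt at 16.1 ± 0.395 and Cd8b1 at 13.1 ± 1.89, but these markers are part of the pattern itself, so their count decides nothing. That source would not bring haemoglobin. Whether the mice themselves, by origin of the cells or by sex and age, differ in these cells was not tested.

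The liver titles and descriptions name opposite mice, and the column headers of the deposited liver values name the same groups as the titles. If the titles were exchanged, the libraries titled cKO would be YFP+ and could carry Rag2, but it averaged 1.14 FPKM in those titled YFP+ and was listed at 0 in those titled cKO. However, Rag2 was also listed at 0 in the 3 thymus YFP+ libraries, so its absence says little of the mouse. Markers of B cells and of DP thymocytes were also higher in the liver libraries titled YFP+. RNA of B-lineage cells may bring Rag2 in either mouse. But the B cell markers named above were Cd74 and 2 MHC class II genes, and that list call was lost in camera with an estimated correlation (adjusted p = 0.0706). RNA of DP thymocytes may also bring Rag2, though cKO mice lose the gene at that stage. Which cells brought it is unknown, so Rag2 does not settle which labels are right. Of genes called in both tissues with median-ratio scaling, 76.1% moved the same way by the titles, where independent lists give 50.3%, and a real difference of direction between the tissues is not ruled out by that share. The titles and the descriptions cannot be told apart by these tests.

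In cKO thymus several Klra genes, Klri2 and Klre1 were higher. In cKO liver Klra7, Klra23, Klra13-ps, Klri2 and Klre1 were higher too, but Klra9 was lower, as was Klra8 (a call lost with median-ratio scaling, adjusted p = 0.0789), and NK receptor genes were 8 higher and 13 lower. Reads shared between Klra copies do not account for the whole pattern, since 5 of the 10 NK receptor genes higher in cKO thymus lie outside that family. Klri2 and Klre1 are among these 5 and were part of the pattern from the start. The count therefore does not say how far shared reads raised the Klra genes themselves. For Klra7, Klra23 and Klra13-ps the thymus fold changes span 0.198, and shared reads may tie them together, which these values leave open. The reporter of the YFP+ mice sits at Rosa26, on the chromosome of the Klra cluster, so DNA of another strain between the loci could also be a source. By the liver titles 5.68% of 88 genes between the loci were called the same way in both tissues, against 4.4% of 8202 others (two-sided Fisher exact p = 0.595, odds ratio 1.31, 95% interval 0.411 to 3.21), which is too wide to decide. By the descriptions it was 4.55% (4 genes) against 0.951% (two-sided Fisher exact p = 0.0111, odds ratio 4.96, 95% interval 1.29 to 13.7). That share goes with this source, but the test left Klr genes out. By the descriptions Klra7, Klra23, Klra13-ps, Klri2 and Klre1 would be higher in cKO thymus and lower in cKO liver, against this source. Klra8 and Klra9 would then be higher in cKO liver. With neither labelling do all these genes move the same way in both tissues. The outcome of the test rests on the unresolved labels, so DNA of another strain stays open as a source. A difference by the origin of the cells, which the design names, stays open and untested.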

How the results depend on the processing

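All alternatives were planned except the removal of the length trend, which was chosen after seeing the data. The thymus count of 1429 genes became 170 with a 2-fold minimum, 801 with no filter on low values (21737 genes tested), 834 with quantile normalization, 789 with median-ratio scaling, 2798 with array weights and 780 with the length trend removed, and 472 to 2408 as each library was left out. The liver count of 2607 became 296 with a 2-fold minimum and 3940 with array weights, and 1539 to 2640 as each library was left out; by the descriptions it is 2607 with every direction reversed, by construction. The count of genes that differ between tissues, 1466, became 330 with a 2-fold minimum, 1167 with a pseudocount of 0.1 and 2634 with array weights. It was 976 to 1704 as each library was left out. With the liver groups by the descriptions it is 3390, or 2249 with median-ratio scaling. The interferon-stimulated list in the thymus turned from 0.13 to an adjusted p of 0.000535 without cKO replicate 1, and its median ranged from -0.65 to 0.40 as each library was left out. The 2-fold minimum was set on fold changes not shifted for the median gene. It lowers a count by its construction, and the cause of the other moves was not tested. Of the values of named genes under the alternatives, 1853 kept direction and call, 131 lost the call, 11 gained it and 3, all of Gata3 in the liver, changed sign without a call. Of those of lists, 409 stayed, 23 lost a call, 27 gained one, 31 moved without a call, and 1 reversed. Without any single library, 41 of 52 named thymus calls, 64 of 69 liver calls and 5 of 5 calls between tissues were kept.

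With the replicate number as a replicate block, the thymus count was 787, the liver count 2214 and the count between tissues 1058. Libraries with the same number did not deviate together (r of deviations from the group means -0.05 to 0.01 in the thymus and -0.06 to 0.07 in the liver), so the numbers do not pair the samples.

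A count tool was not run because the values are FPKM, and the 2 comparisons of liver against thymus were not run because the tables were normalized separately. Absolute depth is unknown, so no limit from counting was set for low genes.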

Other observations

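The gene groups in the next paragraph were put together only after the results of the main tests were seen, with values from the same limma fits, and no other test in this part was planned.

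Of 8 genes of inhibitory and co-stimulatory receptors, 3 passed as lower in cKO thymus and 6 in cKO liver, and none as higher. With median-ratio scaling it was 3 lower in the thymus, and 2 lower and 1 higher in the liver, where the calls of Icos, Tnfrsf18, Cd27 and Cd96 were lost and Tigit passed as higher (adjusted p = 0.0363). Icos, an inducible co-stimulator, was at 8.72 ± 1.40 against 29.0 ± 3.83 FPKM in the thymus (cKO against YFP+, mean ± SD, n = 3; adjusted p = 2.38e-04), and Tnfrsf4, which encodes OX40, at 0.565 ± 0.283 against 6.06 ± 0.652 FPKM in the liver (adjusted p = 1.4e-04). Il2, the T cell growth cytokine, was higher in cKO in both, at 2.56 ± 0.400 against 0.851 ± 0.0777 FPKM in the thymus (adjusted p = 0.00211) and 7.05 ± 1.28 against 1.59 ± 0.825 in the liver (adjusted p = 0.00181). Of the cytokine genes outside the fixed lists, 1 of 5 was higher and 2 lower in the thymus, and 1 of 6 higher and 1 lower in the liver (1 and 1, and 1 and 0, with median-ratio scaling). Among 10 transcription factor genes outside the lists, 3 were higher and 2 lower in cKO thymus, and 5 lower in cKO liver (4 and 2, and 0 and 3, with median-ratio scaling). Ikzf2, which encodes Helios, was at 0.506 ± 0.0937 against 3.51 ± 0.101 FPKM in the thymus and 1.27 ± 0.203 against 4.66 ± 0.0597 in the liver. Klf4, a Krüppel-like factor, moved in opposite ways, at 4.52 ± 1.38 against 0.972 ± 0.557 FPKM in the thymus and 5.53 ± 0.982 against 15.9 ± 2.07 in the liver. Of 8 Gimap genes, GTPases of lymphocyte survival that lie in 1 cluster, 6 were lower in cKO thymus and 5 in cKO liver (5 and 5 with median-ratio scaling), with Gimap6 at 86.9 ± 20.3 against 143 ± 13.8 and 204 ± 4.06 against 388 ± 14.97 FPKM.

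Transcripts of both sexes were read in the liver libraries. Eif2s3y, on the Y chromosome, was at 10.07 ± 0.718 FPKM in cKO and 24.77 ± 0.286 in YFP+ (SD, n = 3), Ddx3y at 8.372 ± 0.0735 and 16.27 ± 1.28, and Xist, made from an inactive X, at 5.669 ± 0.556 and 2.935 ± 0.322. In the thymus Eif2s3y was listed at 0 in all 6 libraries and Xist lay between 3.257 and 4.272 FPKM. These genes were chosen after their values were seen, and no explanation was tested. The labels do not say whether a library was pooled from several mice, and in that case n = 3 counts pools and the SD is between pools.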
